A study of Homo sapiens with 6 samples.

How the data were processed

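The data were 6 gene-level arrays of human naive T cells, activated for 4 days with antibodies to CD3 and CD28. Per the labels, Treg cultures also held TGF-β and interleukin-2, and received DMSO or an EP300/CBP inhibitor at a labelled 4 mM, and Th0 cultures received DMSO. Per the labels' protocols, total RNA was purified on columns with DNase treatment, amplified, labelled with biotin and hybridised to Affymetrix exon arrays. The deposited values are log2 intensities per gene-level row, which the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. The versions and the background and normalization settings are not given in the sources used here. The values were used as deposited. A log2 scale without centring was checked on their range, and no value was missing.

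Groups were taken from the labels (DMSO_Treg, CBPi_Treg and DMSO_Th0, n = 2 arrays each). Array numbers follow the order of the records. Whether arrays are paired across groups is not given in the sources used here, and no blocking factor was fitted. All 22011 rows were tested. Of these 14432 named 1 gene symbol, 2408 named several and 5171 named none, and 14404 of the first kind matched a current symbol in a RefSeq gene table (GRCh38.p14), used for names only. There were 14223 genes with a row of their own, 197 of them with more than 1 row, where the row with the highest mean stood for the gene. EP300, ENTPD1, ITGAE, GAPDH, RPLP0 and EEF1A1 had no row that named them alone and are not reported. No values were printed for 33 rows of genes that tell the sex of a donor.

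The 3 pairwise comparisons were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, a mean per group over all 6 arrays, 3 residual and 2.94 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all rows, with a threshold of 0.05, and SE is limma's moderated standard error. An exact permutation test of 2 against 2 arrays cannot give a two-sided p under 0.333, so p-values rest on limma's model. The 32 gene lists were written from general knowledge before any value was read, and 31 had the 5 measured genes needed for a test. They were tested with limma's camera at a preset correlation of 0.01, and also with an estimated correlation and with fry, with adjustment over the lists of a comparison. With an estimated correlation camera takes its p-value from the 3 residual degrees of freedom, which leaves it little power. The estimates ran from −0.0596 for natural killer cell markers to 0.547 for cell cycle. Where they exceed 0.01, the preset p-values treat members as closer to independent than estimated. List genes were also adjusted over the list alone. Totals of genes over all lists pool these separate adjustments, so the threshold of 0.05 does not hold for such totals. A gene in several lists was tested in each.

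Genes were named by a rule set beforehand: up to 12 of the largest called rises and falls per comparison, up to 4 members per list that passed, and a fixed set of T cell, coactivator and control genes. A list member was taken as passing where it passed adjusted over the list alone. Genes named beyond this rule, such as CD226, CD101 and the genes called with a single row per gene, were chosen after their values were seen.

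Alternatives set beforehand were quantile normalization, median centring of each array, leaving out rows with a mean under the 30th percentile (dim rows), a single row per gene, an intensity trend with robust settings, only the 4 compared arrays, array quality weights, a 1.5-fold minimum and leaving out each array in turn. With a group reduced to a single array, that array was assumed to vary like the others. For gene lists the mean of all rows of a gene was also used. Cyclic loess normalization and leaving out 2 deviating arrays together were added after the data had been seen. The correlation between comparisons that share arrays was set against 100 simulated data sets of unchanged groups, with a pooled spread and with each group's own, and against fits that used a different DMSO_Treg array in each comparison.

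The fit was tested on simulated data with the residual spread pooled over the 3 groups, in 5 runs with 200 changed rows among 22011. It recovered 208 of 500 2-fold and 415 of 500 4-fold changes, with 22 false calls. At an unadjusted p under 0.05, camera picked up a list of 30 genes shifted by −0.5 in 5 of 5 runs and an unshifted list in 0 of 5. This is looser than the adjusted p used for list calls elsewhere. The simulated genes varied independently of each other. These runs therefore do not test the preset correlation on lists whose members vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probe-level intensities, detection calls and quality measures of the arrays were not used here, and batches are not given in the sources used here.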

Results

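Gene expression was measured on 6 human exon arrays, summarised to 22011 gene-level rows on a log2 scale, in 3 groups of 2 arrays. Naive T cells were activated through CD3 and CD28 for 4 days. Treg cultures also held TGF-β and interleukin-2, a cytokine mixture that induces FOXP3 and a regulatory T cell phenotype, and Th0 cultures held neither. Treg cultures received the solvent DMSO (DMSO_Treg) or an inhibitor of the bromodomains of CBP and EP300 (CBPi_Treg), which are paired histone acetyltransferases and transcriptional coactivators. Th0 cultures received DMSO (DMSO_Th0). The inhibitor dose is labelled as 4 mM, a value that could not be checked here, and its time of addition is not given in the sources used here. The labels do not say that the arrays of a group came from separate cultures or donors, so p-values measure only the spread between these arrays. Array medians lay between 6.87 and 6.99, and replicate arrays correlated across rows at r = 0.994 for DMSO_Treg, 0.989 for CBPi_Treg and 0.988 for DMSO_Th0. Array numbers, as in DMSO_Treg 1, only name the arrays. Gene groups are lists fixed before the data were examined. Unless all rows are named, a gene is said to have risen or fallen where it passed limma's test at an adjusted p of 0.05, adjusted over the list alone. For each gene named as risen or fallen, both arrays of one group lay beyond both of the other. Genes picked out below for keeping their pass with each of the 6 arrays left out in turn were chosen after their values were seen.

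The first comparison asked what the inhibitor changed in Treg cultures (CBPi_Treg minus DMSO_Treg). FOXP3, the transcription factor that defines regulatory T cells, stood at 9.64 ± 0.08 (SD, n = 2) in DMSO and 8.28 ± 0.02 (SD, n = 2) with the inhibitor, and fell by 1.36 on the log2 scale (SE 0.15). LAG3, an inhibitory receptor that binds MHC class II, fell by 1.64 (SE 0.13), from 10.07 ± 0.10 to 8.42 ± 0.08 (SD, n = 2). HAVCR2, which encodes the inhibitory receptor TIM-3, fell from 9.24 ± 0.06 to 7.64 ± 0.10 (SD, n = 2). ICOS, a costimulatory receptor, fell by 1.15 (SE 0.20). Of the 33 measured genes of the Treg signature 9 fell, 0 rose and 24 did not pass, adjusted over the list alone, and 0 passed over all rows. The list lay lower than other genes by camera at adjusted p = 1.02e-06, and at adjusted p = 0.278 with an estimated correlation. Within it the adjusted p over the list alone was 0.00199 for FOXP3 and 0.000625 for LAG3, against 0.181 and 0.104 over all rows. Both genes kept that pass with each of the 6 arrays left out. The count of 9 dropped to 2 without DMSO_Treg 1, 2 without DMSO_Treg 2 and 4 without CBPi_Treg 1. CTLA4, the inhibitory receptor that competes for CD80 and CD86, was lower by −0.78 (SE 0.18) and passed over the list alone (adjusted p = 0.0266), but not without DMSO_Treg 1 (−0.75), DMSO_Treg 2 (−0.80) or CBPi_Treg 1 (−0.57). Other fixed Treg genes did not pass: IL2RA, the high-affinity interleukin-2 receptor chain, stood at 0.08 (SE 0.19), TIGIT at −0.29 (SE 0.13), TNFRSF18 at −0.33 (SE 0.13) and IL10 at 0.11 (SE 0.13). IKZF2 stood at −0.01 (SE 0.12), and its sign turned when each array was centred on its median (0.04).

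Among 30 measured costimulatory and inhibitory receptors, 10 fell, 0 rose and 20 did not pass, adjusted over the list alone, with 0 over all rows (adjusted p = 4.42e-10 by camera, and adjusted p = 0.271 with an estimated correlation). Besides LAG3, HAVCR2 and ICOS they included CD80, a ligand of CD28 and CTLA4, at −1.40 (SE 0.19), the activating receptor CD226 at −0.96 (SE 0.17) and CD160 at −0.70 (SE 0.12). Each of these 6 kept its pass in this list with each array left out, but in the Treg signature ICOS did not pass without DMSO_Treg 1 or DMSO_Treg 2. Chemokine receptors and homing genes had 6 falls, 0 rises and 14 genes of 20 that did not pass, adjusted over the list alone, and 0 over all rows (adjusted p = 2.27e-05, and adjusted p = 0.278 with an estimated correlation). CXCR5, the follicle-homing receptor, fell by 1.43 (SE 0.21), GPR183, an oxysterol receptor, fell by 1.29 (SE 0.15) and CXCR4 fell by 0.86 (SE 0.14), each also with any array left out in this list. Among Tfh genes CXCR5 did not pass without DMSO_Treg 1. Without DMSO_Treg 1 the homing list had 3 falls and 1 rise.

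Of 17 measured Th1 genes, 10 fell, 0 rose and 7 did not pass, adjusted over the list alone, and 0 passed over all rows (adjusted p = 3.27e-11, and adjusted p = 0.271 with an estimated correlation). IL2, the T cell growth factor, fell by 1.96 (SE 0.34), IFNG, the Th1 cytokine interferon-γ, fell by 0.94 (SE 0.20), TNF fell by 0.98 (SE 0.19), LTA, a related cytokine, fell by 0.76 (SE 0.14) and the chemokine receptor CXCR3 fell by 0.75 (SE 0.14). All 5 kept their pass in the Th1 list with each array left out, and the Th1 count stayed within 1.5 times. In other lists some did not. IL2 and TNF did not pass in the T cell receptor early response without DMSO_Treg 1, DMSO_Treg 2 or CBPi_Treg 1. CXCR3 did not pass among homing genes without DMSO_Treg 1. TBX21, the Th1 transcription factor T-bet, stood at −0.22 (SE 0.16) and did not pass over all rows (adjusted p = 0.999). Of the T cell receptor early response, 9 of 26 genes fell, 0 rose and 17 did not pass, adjusted over the list alone, with 0 over all rows (adjusted p = 3.95e-08, and adjusted p = 0.278 with an estimated correlation). Its member SPRY1, a feedback regulator of receptor signalling, fell by 1.75 (SE 0.13) from 10.55 ± 0.03 to 8.81 ± 0.15 (SD, n = 2). Without DMSO_Treg 1, DMSO_Treg 2 or CBPi_Treg 1 the early response list had 1 fall. IRF4, a transcription factor induced by receptor signalling, stood at −0.44 (SE 0.15, adjusted p = 0.794 over all rows).

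Of 24 interleukin-2 and STAT5 targets, 15 fell, 0 rose and 9 did not pass, adjusted over the list alone, and 0 passed over all rows (adjusted p = 1.56e-15, and adjusted p = 0.271 with an estimated correlation). The estimated correlation was 0.345 against the preset 0.01, so the smaller p-value overstates the evidence if that estimate holds. LIF, a cytokine of the interleukin-6 family, fell by 1.43 (SE 0.16) and MYC, a growth-promoting transcription factor, fell by 0.83 (SE 0.17). The count of 15 was 2 without DMSO_Treg 1, which also ended the pass of MYC, 8 without DMSO_Treg 2 and 5 without CBPi_Treg 2. Th17 genes had 3 falls and 14 genes of 17 that did not pass, adjusted over the list alone, and 0 over all rows (adjusted p = 3.6e-06, and adjusted p = 0.271 with an estimated correlation). Among them CCL20, the ligand of CCR6, fell by 1.31 (SE 0.16). The Th17 count was 1 without DMSO_Treg 1, DMSO_Treg 2 or CBPi_Treg 1, and 6 without DMSO_Th0 1 or DMSO_Th0 2. Of 14 Tfh genes, 4 fell and 10 did not pass, adjusted over the list alone, with 0 over all rows (adjusted p = 1.2e-07, and adjusted p = 0.278 with an estimated correlation), against 0 falls without DMSO_Treg 1 and 1 without DMSO_Treg 2. The Th2 genes did not shift as a group (adjusted p = 0.101), and LIF was the only one of 15 to pass, adjusted over the list alone. GATA3, the Th2 transcription factor, stood at 0.25 (SE 0.15) and did not pass.

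Cytotoxic effector genes had 6 falls, 1 rise and 8 genes of 15 that did not pass, adjusted over the list alone, and 0 over all rows (adjusted p = 1.84e-05, and adjusted p = 0.271 with an estimated correlation). FGFBP2, a marker of cytotoxic lymphocytes, had the largest fall among the named genes: it stood at 9.39 ± 0.08 in DMSO and 6.82 ± 0.04 with the inhibitor (SD, n = 2), a log2 change of −2.57 (SE 0.18). CST7, the cystatin F gene, fell by 1.35 (SE 0.16). FGFBP2 and CST7 passed with each array left out, while the list had 2 falls without DMSO_Treg 1 or CBPi_Treg 1 and 3 without DMSO_Treg 2 or CBPi_Treg 2. KLRG1, an inhibitory receptor of differentiated lymphocytes, was higher by 0.79 (SE 0.15), a rise lost without DMSO_Treg 1, DMSO_Treg 2 or CBPi_Treg 2. The natural killer cell markers did not shift as a group as deposited (adjusted p = 0.0538), but did after quantile normalization (0.00834), cyclic loess (0.0141), median centring (0.0445), a filter on dim rows (0.0497) or without DMSO_Treg 2 (0.0427). With all arrays as deposited it stood at adjusted p = 0.278 with an estimated correlation. In that list NCR3 fell by 0.97 (SE 0.15) and IL18RAP fell by 1.17 (SE 0.20), while 8 of 10 genes did not pass, adjusted over the list alone. CD8 and gamma-delta T cell markers had 4 measured genes, too few for a list test, and 0 of them passed.

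Of 28 genes of the glycolysis and hypoxia response, 12 fell, 0 rose and 16 did not pass, adjusted over the list alone, and 0 passed over all rows (adjusted p = 3.11e-15, and adjusted p = 0.271 with an estimated correlation). ADM, the hypoxia-induced peptide adrenomedullin, fell by 1.12 (SE 0.13) and ALDOC, a glycolytic aldolase, fell by 0.83 (SE 0.15). That count was 0 without DMSO_Treg 1, 1 without DMSO_Treg 2, 4 without CBPi_Treg 1, 2 without CBPi_Treg 2, and 5 after quantile normalization, median centring or cyclic loess. Of 34 genes of the TGF-beta and SMAD response, 8 fell and 26 did not pass, adjusted over the list alone, and 0 over all rows (adjusted p = 7.42e-07, and adjusted p = 0.278 with an estimated correlation). THBS1, the matrix protein thrombospondin-1, fell by 0.96 (SE 0.14), and RHOB, a small GTPase, fell by 0.94 (SE 0.14). The TGF-beta count was 0 without DMSO_Treg 1, DMSO_Treg 2 or CBPi_Treg 1, 4 without CBPi_Treg 2, 3 without DMSO_Th0 1 or DMSO_Th0 2, and 5 after quantile normalization. Interferon-stimulated genes had 8 falls and 28 genes of 36 that did not pass, adjusted over the list alone, with 0 over all rows (adjusted p = 4.42e-10, and adjusted p = 0.278 with an estimated correlation). IFIT2 and IFI44L fell by 1.05 (SE 0.14) and 1.41 (SE 0.21), and the count was 0 without DMSO_Treg 1, 5 without DMSO_Treg 2 and 4 without CBPi_Treg 1.

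NF-kappaB targets had 5 falls, 1 rise and 18 genes of 24 that did not pass, adjusted over the list alone (adjusted p = 1.13e-06, and adjusted p = 0.281 with an estimated correlation). The rise was that of CCL22, the ligand of CCR4, by 0.80 (SE 0.17). The falls and the rise were 0 without DMSO_Treg 1, DMSO_Treg 2 or CBPi_Treg 1, CCL22 also did not pass without CBPi_Treg 2, and the falls were 2 after quantile normalization or cyclic loess and 3 after median centring. Naive and quiescence genes had 3 falls among 21 (adjusted p = 0.000263, and adjusted p = 0.399 with an estimated correlation), adjusted over the list alone, and 0 without DMSO_Treg 1, DMSO_Treg 2 or CBPi_Treg 1. Cholesterol biosynthesis genes had 1 fall among 16, that of the synthase HMGCS1 by 1.08 (SE 0.21), adjusted over the list alone (adjusted p = 1.58e-06 for the list, and adjusted p = 0.278 with an estimated correlation), and 0 falls without any array but CBPi_Treg 2. The CD4 T cell markers (adjusted p = 0.00416) and heat shock genes (adjusted p = 0.00655) lay lower as lists with 0 members passing, at adjusted p = 0.449 and adjusted p = 0.278 with an estimated correlation, and heat shock lost its call without DMSO_Treg 2 (0.11). Genes raised by BET bromodomain inhibitors lay lower (adjusted p = 0.0284, and adjusted p = 0.473 with an estimated correlation), lost without DMSO_Treg 1 (0.147) or CBPi_Treg 1 (0.181). MYC targets and ribosome biogenesis and p53 targets were both at adjusted p = 0.0437 (adjusted p = 0.668 and adjusted p = 0.467 with an estimated correlation). The first was lost without DMSO_Treg 1 (0.116), CBPi_Treg 1 (0.16) or either DMSO_Th0 array (0.0596), and the other without DMSO_Treg 1 (0.116) or CBPi_Treg 2 (0.183). Quantile normalization, cyclic loess and the filter on dim rows also ended both, at 0.099, 0.114 and 0.147 for MYC targets and ribosome biogenesis and at 0.14, 0.119 and 0.0848 for p53 targets.

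Other lists did not pass with all arrays as deposited. These were cell cycle (adjusted p = 0.117), fatty acid synthesis (0.0692), the amino acid and ATF4 response (0.292), acetyltransferases, deacetylases and bromodomain proteins (0.557), MHC class II (0.557), B cell markers (0.97), monocyte and dendritic cell markers (0.757), red cell and platelet markers (0.454) and housekeeping genes (0.486). The amino acid and ATF4 response lay higher after quantile normalization (adjusted p = 0.0394) or cyclic loess (0.0368), cell cycle lay lower without CBPi_Treg 2 (0.0399), and fatty acid synthesis lay lower without CBPi_Treg 1 (0.0245) or either DMSO_Th0 array (0.0421). In this order they stood at adjusted p = 0.796, adjusted p = 0.796 and adjusted p = 0.569 with an estimated correlation, all arrays as deposited. CREBBP, which encodes CBP, stood at 9.59 ± 0.02 in DMSO and 9.78 ± 0.02 with the inhibitor (SD, n = 2; adjusted p = 0.999 over all rows). Of the control genes, ACTB stood at −0.06 (SE 0.24), B2M at 0.01 (SE 0.13), TFRC at −0.62 (SE 0.20), SDHA at −0.34 (SE 0.21), YWHAZ at 0.17 (SE 0.32) and TBP at −0.13 (SE 0.18), with none past the threshold. PPIA (−0.03), HPRT1 (−0.10), GUSB (−0.03) and PGK1 (−0.04) changed sign under 1 or more of quantile normalization, median centring and cyclic loess.

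**Figure D1:**
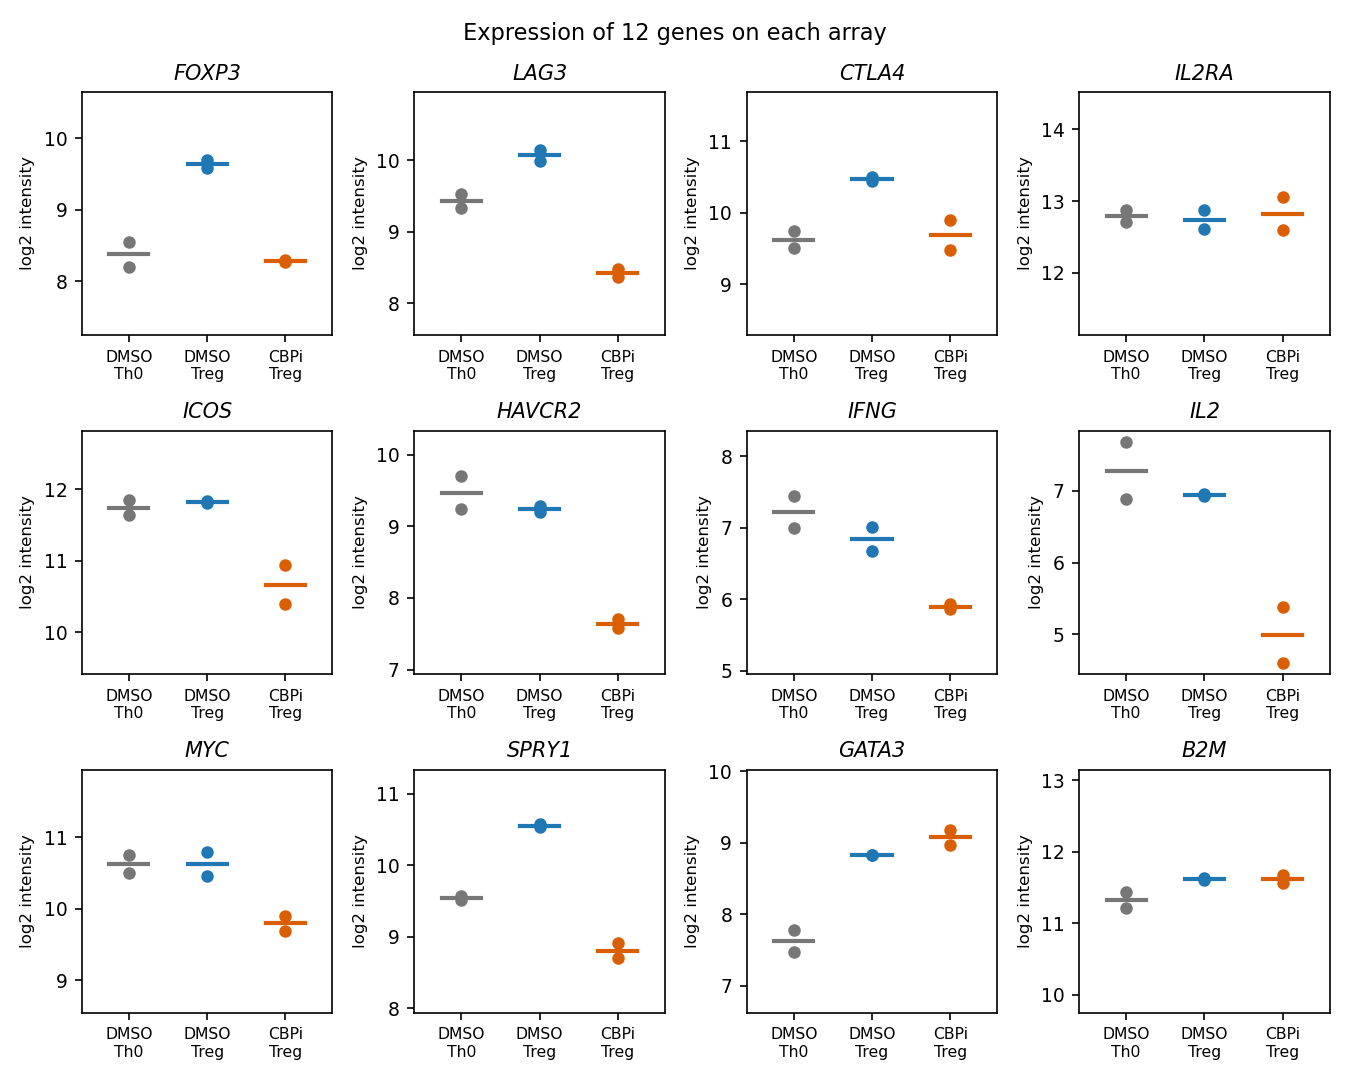
Deposited log2 expression of 12 genes in the 6 arrays, with 1 point per array and a bar at each group's mean for DMSO_Treg, CBPi_Treg and DMSO_Th0. FOXP3 averaged 9.64, 8.28 and 8.38 in these groups and LAG3 10.07, 8.42 and 9.43, while IL2RA averaged 12.74, 12.82 and 12.79 with overlapping points.

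Over all 22011 rows, limma called 0 rows for the inhibitor, with a smallest adjusted p of 0.104. At an unadjusted p under 0.05 there were 1268 rows against 1100.55 from chance, of which 950 were lower and 318 higher with the inhibitor. From the 4 compared arrays alone there were 1695, as the shared spread also takes in the DMSO_Th0 arrays, which varied most. Both arrays of one group lay above both of the other in 37.4% of rows, against 33.3% by chance. Other settings called 1 row after quantile normalization or cyclic loess, 3 after median centring, 4 after a filter on dim rows or with array weights, and 0 with trend and robust settings, from the 4 compared arrays, or without any array. With a single row for each of 14223 genes, 17 genes were called and all 17 were lower, among them FGFBP2, SPRY1, LAG3, HAVCR2, LIF, FOXP3, CST7, CCL20, GPR183 and ADM, and also the adhesion receptor ADGRG1 (−1.68) and the neuronal protein NRN1 (−1.06). On simulated data with the spread pooled over the 3 groups and 200 changed rows per run, 41.6% of 2-fold and 83% of 4-fold changes were called. With fewer changed rows the adjustment is stricter, so these shares do not tell what could have been called here among 22011 rows. Of 575 distinct genes in the lists, 91 fell and 2 rose, adjusted over the list alone, with 23 falls without DMSO_Treg 1, 37 without DMSO_Treg 2, 43 without CBPi_Treg 1 and 63 without CBPi_Treg 2. There were 22 genes that passed in a list with each of the 6 arrays left out, and all 22 were lower. The totals of 91 and 2 pool lists that were adjusted separately, so the threshold of 0.05 does not hold for them as a whole. Camera called 20 of 31 lists lower and 0 higher, 0 with an estimated correlation, while fry called the cytotoxic list alone for a common direction (adjusted p = 0.0407). The test with an estimated correlation had little power, so calls lost under it do not show that members vary together. Th17 genes lost theirs at an estimated correlation of −0.0283, below the preset 0.01. The mixed test of fry, which takes changes in either direction, passed 18 lists.

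**Figure D2:**
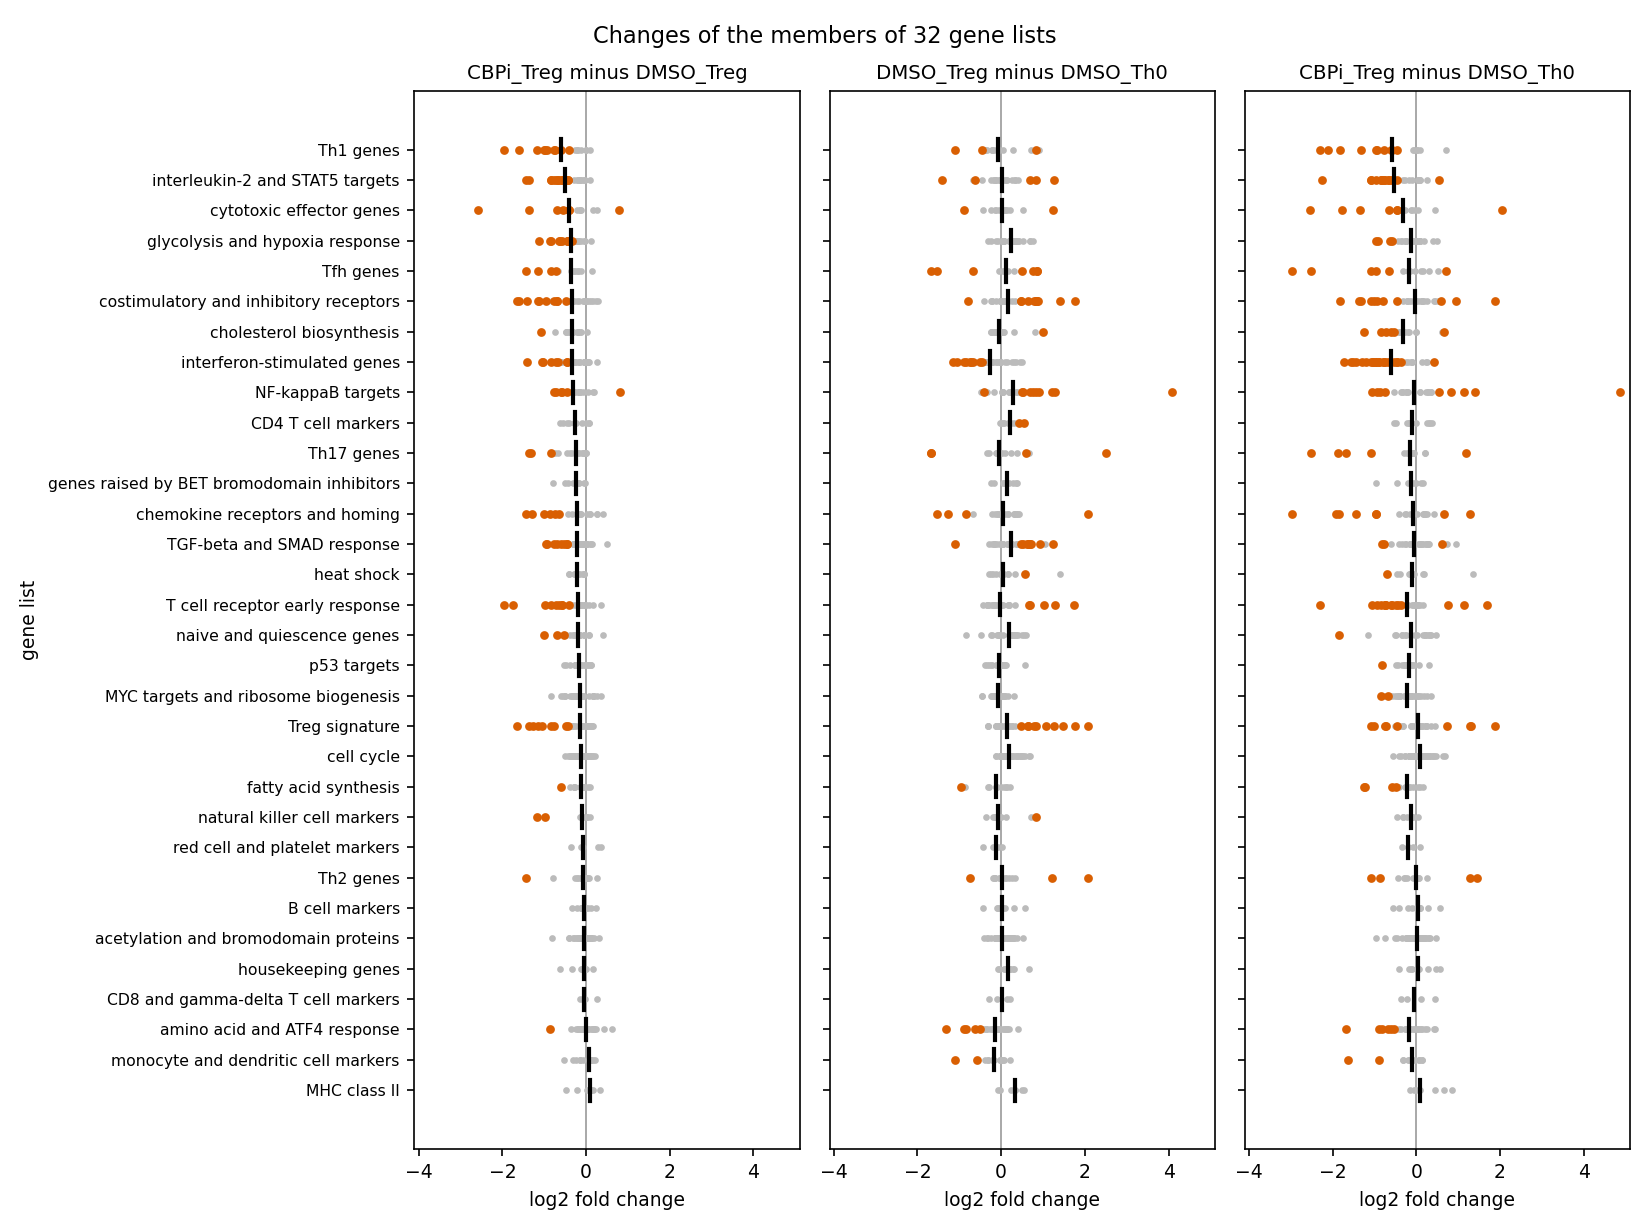
Log2 changes of the members of 32 gene lists in the 3 comparisons, with a grey point per gene, an orange point where a gene passed adjusted over the list alone, and a black tick at the list median. With the inhibitor the medians were −0.61 for Th1 genes, −0.51 for interleukin-2 and STAT5 targets and −0.37 for the glycolysis and hypoxia response, against −0.05 for housekeeping genes, and the median of acetyltransferases, deacetylases and bromodomain proteins turned from −0.06 to 0.02 after quantile normalization and 0.01 after cyclic loess.

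The second comparison asked what the TGF-β and interleukin-2 culture changed relative to Th0, both in DMSO (DMSO_Treg minus DMSO_Th0). CCL22, a chemokine for CCR4-bearing cells, stood at 11.22 ± 0.19 in Treg and 7.15 ± 0.20 in Th0 cultures (SD, n = 2), and rose by 4.07 (SE 0.17, adjusted p = 0.00766 over all rows). FOXP3 was higher by 1.26 (SE 0.15, adjusted p = 0.0866 over all rows and 0.00153 over the list alone). Of the 33 genes of the Treg signature 10 rose, 0 fell and 23 did not pass, adjusted over the list alone, and 1 rose over all rows (adjusted p = 2.79e-05, and adjusted p = 0.674 with an estimated correlation). That gene was IKZF4, an Ikaros-family partner of FOXP3, which rose by 1.47 (SE 0.13, adjusted p = 0.0463 over all rows). CCR4, a chemokine receptor of regulatory and Th2 cells, rose by 2.06 (SE 0.25), TNFRSF9, the costimulatory receptor 4-1BB, rose by 1.78 (SE 0.19) and CD101 rose by 1.06 (SE 0.15). FOXP3, IKZF4, CCR4, TNFRSF9 and CD101 passed over the list alone with each array left out. The count of 10 was 5 without DMSO_Treg 1, DMSO_Treg 2 or DMSO_Th0 1. LAG3 (0.63, SE 0.13) and CTLA4 (0.84, SE 0.18) also passed over the list alone, both at adjusted p = 0.012, and were not among the 20 genes that passed with each array left out.

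Genes of the TGF-beta and SMAD response had 9 rises, 1 fall and 24 genes of 34 that did not pass, adjusted over the list alone, and 0 over all rows (adjusted p = 2.79e-05, and adjusted p = 0.674 with an estimated correlation). THBS1 rose by 1.24 (SE 0.14) and PMEPA1, a feedback inhibitor of TGF-β signalling, rose by 0.92 (SE 0.13), while SMAD3, a signal transducer of TGF-β, fell by 1.11 (SE 0.15). The 9 rises were 1 without DMSO_Treg 1, 2 without DMSO_Treg 2 and 3 without DMSO_Th0 1, and PMEPA1 did not pass without DMSO_Treg 1. Costimulatory and inhibitory receptors had 10 rises and 1 fall among 30, adjusted over the list alone (adjusted p = 3.11e-05, and adjusted p = 0.674 with an estimated correlation), with CD80 at 1.40 (SE 0.19) and CD160 at 0.84 (SE 0.12). Those 10 rises were 3 without DMSO_Treg 1 and 4 without DMSO_Treg 2 or DMSO_Th0 1, and the fall was lost without DMSO_Treg 1, DMSO_Treg 2 or DMSO_Th0 2. The NF-kappaB targets had 9 rises, CCL22 among them, and 1 fall among 24, adjusted over the list alone, and CCL22 alone over all rows (adjusted p = 2.79e-05, and adjusted p = 0.674 with an estimated correlation). These rises were 1 without DMSO_Treg 1, DMSO_Treg 2 or DMSO_Th0 1, and the fall was lost without any array. After quantile normalization or cyclic loess 4 of these genes fell, and 3 after median centring.

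Interferon-stimulated genes were lower in Treg than in Th0 cultures: 9 fell, 0 rose and 27 of 36 did not pass, adjusted over the list alone, with 0 over all rows (adjusted p = 5.18e-08, and adjusted p = 0.674 with an estimated correlation). MX1, MX2 and OAS1, antiviral effectors, fell by 0.84 (SE 0.12), 1.05 (SE 0.14) and 0.88 (SE 0.11), and the list had 3 falls without DMSO_Treg 1, 0 without DMSO_Treg 2 and 5 without DMSO_Th0 2. The amino acid and ATF4 response had 5 falls among 27, adjusted over the list alone (adjusted p = 0.000146, and adjusted p = 0.674 with an estimated correlation), among them the transsulfuration enzyme CTH at −1.32 (SE 0.27). There were 0 such falls without any array but DMSO_Th0 1, and 8 after quantile normalization or cyclic loess. The monocyte and dendritic cell markers lay lower (adjusted p = 0.00385, and adjusted p = 0.674 with an estimated correlation), with ITGAX at −1.11 (SE 0.16) and CD68 at −0.58 (SE 0.12) the 2 members that passed. That list call was lost without DMSO_Th0 1 (0.353), and its 2 falls were 1 without DMSO_Treg 1 or DMSO_Th0 2 and 0 without DMSO_Treg 2. The cell cycle list (adjusted p = 0.0001) and the glycolysis and hypoxia response (adjusted p = 7.63e-05) lay higher with 0 members passing, at adjusted p = 0.829 and adjusted p = 0.674 with an estimated correlation, and cell cycle lost its call without DMSO_Th0 1 (0.481). CD4 T cell markers lay higher (adjusted p = 0.00753, and adjusted p = 0.764 with an estimated correlation) and lost the call without DMSO_Th0 1 (0.206), after quantile normalization (0.0753) or after cyclic loess (0.0961).

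Lists of other T cell fates did not shift as groups, and held members that moved in both directions. Tfh genes had 4 rises and 3 falls among 14, and interleukin-2 and STAT5 targets 3 rises and 2 falls among 24, adjusted over the list alone. GATA3 rose by 1.20 (SE 0.15) and MAF, another regulator of Th2 cytokines, fell by 0.75 (SE 0.12), in a Th2 list at adjusted p = 0.364. CCL20 rose by 2.49 (SE 0.16, adjusted p = 0.0176 over all rows) and IL21, a cytokine of Th17 and Tfh cells, fell by 1.68 (SE 0.20) among Th17 genes (adjusted p = 0.989), and CXCR5 fell by 1.53 (SE 0.21) among Tfh genes (adjusted p = 0.474). DUSP4, a MAP kinase phosphatase, rose by 1.75 (SE 0.12, adjusted p = 0.0176 over all rows) in the T cell receptor early response (adjusted p = 0.526), SELPLG, the P-selectin ligand, fell by 1.28 (SE 0.15) among homing genes (adjusted p = 0.999), and SOCS3, a feedback inhibitor of cytokine signalling, fell by 1.40 (SE 0.18) among interleukin-2 and STAT5 targets (adjusted p = 0.989). Each of these 8 genes passed over its list alone with each array left out. KLRG1, in a cytotoxic list at adjusted p = 0.989, did so too, with a rise of 1.25 (SE 0.15). Th1 genes (adjusted p = 0.281), naive and quiescence genes (0.087), cholesterol biosynthesis (0.989), heat shock (0.788), acetyltransferases, deacetylases and bromodomain proteins (0.766), genes raised by BET bromodomain inhibitors (0.281), B cell markers (0.91), natural killer cell markers (0.989) and housekeeping genes (0.122) did not pass. MYC targets and ribosome biogenesis (adjusted p = 0.087) lay lower after quantile normalization (0.0156), cyclic loess (0.00705), the filter on dim rows (0.0419) or without DMSO_Th0 1 (0.00257), and fatty acid synthesis (adjusted p = 0.0901) did so at 0.0173, 0.0217, 0.0419 and 0.0241. With all arrays as deposited these stood at adjusted p = 0.832 and adjusted p = 0.829 with an estimated correlation. MHC class II (adjusted p = 0.055) lay higher after quantile normalization (0.0289), median centring (0.0307), cyclic loess (0.0299) or without either CBPi_Treg array (0.0407), p53 targets (0.249) lay lower after cyclic loess (0.0464), and red cell and platelet markers (0.102) lay lower without DMSO_Th0 2 (0.0191). In the same way these stood at adjusted p = 0.674, adjusted p = 0.829 and adjusted p = 0.674 with an estimated correlation. IFNG stood at −0.38 (SE 0.20), IL2RA at −0.04 (SE 0.19) and MYC at 0.00 (SE 0.17), with the sign of MYC turning under quantile normalization (−0.10), median centring (−0.01) and cyclic loess (−0.10).

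Over all rows limma called 15 rows between Treg and Th0 cultures, 12 higher and 3 lower in Treg, and 13 of them named a single gene. Besides CCL22, CCL20, DUSP4 and IKZF4 the genes that rose were CHN1 (2.68, SE 0.21), the myosins MYO5B (2.24, SE 0.15) and MYO1E (2.23, SE 0.16), NRN1 (2.03, SE 0.11), the intermediate filament VIM (1.66, SE 0.12) and PTGS1, which encodes cyclooxygenase-1 (1.38, SE 0.11). PRG4, the lubricant lubricin, fell by 3.30 (SE 0.22, adjusted p = 0.0176), ENPP2, the enzyme autotaxin, fell by 2.10 (SE 0.17, adjusted p = 0.0368) and RNF213, a ubiquitin ligase, fell by 1.58 (SE 0.14, adjusted p = 0.0463), with its other row at −1.29 (adjusted p = 0.0842). There were 1725 rows at an unadjusted p under 0.05, and both arrays of one group lay above both of the other in 36.5% of rows against 33.3% by chance. The lower share of called rows was 20% as deposited, 42.6% of 61 rows after quantile normalization, 35.9% of 64 after median centring and 41.2% of 51 after cyclic loess, and all 15 rows were among the calls in each. Without either DMSO_Treg array or either DMSO_Th0 array 0 rows were called, and without either CBPi_Treg array 8. Of 575 list genes 49 rose and 31 fell, adjusted over the list alone, against 14 and 11 without DMSO_Treg 1, 17 and 6 without DMSO_Treg 2, 19 and 26 without DMSO_Th0 1 and 49 and 14 without DMSO_Th0 2. Camera called 7 of 31 lists higher and 3 lower, with 0 by an estimated correlation and 0 by fry for a common direction (smallest adjusted p = 0.188). The mixed test of fry, which takes changes in either direction, passed 19 lists.

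The third comparison set the inhibitor-treated Treg cultures against Th0 cultures (CBPi_Treg minus DMSO_Th0), where culture and inhibitor differ together. A gene that passed here and not in another comparison is not shown to differ between them. FOXP3 did not differ past the threshold, at 8.28 ± 0.02 and 8.38 ± 0.25 (SD, n = 2; −0.10, SE 0.15, adjusted p = 0.898 over all rows), nor did CTLA4 (0.07, SE 0.18, adjusted p = 0.948). CCL22 rose by 4.87 (SE 0.17, adjusted p = 0.00264 over all rows) and GATA3 rose by 1.45 (SE 0.15, adjusted p = 0.034). Of 36 interferon-stimulated genes, 21 fell, 1 rose and 14 did not pass, adjusted over the list alone, and 6 fell over all rows (adjusted p = 9.18e-17, and adjusted p = 0.464 with an estimated correlation), including IFIT2 by 1.56 (SE 0.14) and MX2 by 1.45 (SE 0.14). The 21 falls were 13 without CBPi_Treg 1, and the rise was lost without any array but DMSO_Th0 2. Of 17 Th1 genes, 10 fell and 0 rose, adjusted over the list alone, and HAVCR2 fell over all rows by 1.83 (SE 0.18, adjusted p = 0.029), with the list at adjusted p = 1.57e-07, and adjusted p = 0.464 with an estimated correlation. IL12RB2, an interleukin-12 receptor chain, fell by 2.10 (SE 0.26) and IFNG fell by 1.32 (SE 0.20).

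Interleukin-2 and STAT5 targets had 13 falls and 1 rise among 24, adjusted over the list alone, and 1 fall over all rows, where SOCS3 fell by 2.25 (SE 0.18, adjusted p = 0.0163), with the list at adjusted p = 1.42e-07, and adjusted p = 0.633 with an estimated correlation. That rise was lost without CBPi_Treg 1 or DMSO_Th0 1. The T cell receptor early response had 12 falls and 3 rises among 26, adjusted over the list alone (adjusted p = 0.00356, and adjusted p = 0.648 with an estimated correlation), with IER3, an early survival gene, at −1.06 (SE 0.12, adjusted p = 0.0416 over all rows) and DUSP4 at 1.70 (SE 0.12, adjusted p = 0.0123 over all rows). Cytotoxic effector genes had 6 falls and 1 rise among 15, adjusted over the list alone (adjusted p = 0.00211, and adjusted p = 0.464 with an estimated correlation), and 3 falls without DMSO_Th0 2. Over all rows FGFBP2 fell by 2.54 (SE 0.18, adjusted p = 0.0123), CST7 fell by 1.78 (SE 0.16, adjusted p = 0.025) and KLRG1 rose by 2.04 (SE 0.15, adjusted p = 0.0123). Th17 genes (adjusted p = 0.02, and adjusted p = 0.497 with an estimated correlation) had 4 falls and 1 rise among 17 and Tfh genes (adjusted p = 0.0435, and adjusted p = 0.718 with an estimated correlation) 5 falls and 1 rise among 14, adjusted over the list alone. IL21 fell by 2.52 (SE 0.20, adjusted p = 0.015) and CXCR5 fell by 2.96 (SE 0.21, adjusted p = 0.0123) over all rows. The Th17 call was lost without CBPi_Treg 1 (0.0514), DMSO_Th0 1 (0.0853) or dim rows (0.11), and the Tfh rise without CBPi_Treg 2. The Tfh call was lost without CBPi_Treg 1 (0.106), DMSO_Th0 1 (0.0694), DMSO_Th0 2 (0.201) or dim rows (0.0795).

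Several further lists had camera calls in this comparison that were lost without single arrays. Some counts of falls also dropped without a DMSO_Treg array, which enters this comparison only through the shared estimate of the spread. Cholesterol biosynthesis had 5 falls and 1 rise among 16, with HMGCS1 at −1.26 (SE 0.21), and MYC targets and ribosome biogenesis had 2 falls among 30, adjusted over the list alone, both lists at adjusted p = 0.00356 (adjusted p = 0.648 and adjusted p = 0.704 with an estimated correlation). Without DMSO_Th0 2 the first had 0 falls and adjusted p = 0.137, and the other 0 falls and adjusted p = 0.156. The cholesterol rise was lost without any array but CBPi_Treg 1, its falls were 3 without CBPi_Treg 1 and 2 without CBPi_Treg 2, and the 2 falls among MYC targets were 0 without any of the 6 arrays. Fatty acid synthesis (4 falls among 12, adjusted p = 0.00736), glycolysis and hypoxia response (4 among 28, adjusted p = 0.00982), p53 targets (1 among 18, adjusted p = 0.00982) and the amino acid and ATF4 response (6 among 27, adjusted p = 0.0138) had those falls adjusted over the list alone. With an estimated correlation they stood at adjusted p = 0.648, adjusted p = 0.704, adjusted p = 0.648 and adjusted p = 0.718. In the same order the calls were lost at 0.0737, 0.117, 0.058 and 0.0737 without CBPi_Treg 2 and at 0.0707, 0.122, 0.156 and 0.189 without DMSO_Th0 2. Falls of p53 targets were 0 without any array, and those of fatty acid synthesis were 1 without either DMSO_Treg array or DMSO_Th0 2, 0 without CBPi_Treg 1 and 2 without CBPi_Treg 2. Glycolysis falls were 2 without either DMSO_Treg array, CBPi_Treg 1 or DMSO_Th0 1 and 0 without CBPi_Treg 2, and ATF4 response falls were 2 without either DMSO_Treg array, CBPi_Treg 1 or DMSO_Th0 2. The cell cycle list lay higher (adjusted p = 0.0304, and adjusted p = 0.901 with an estimated correlation) with 0 members passing. That call was lost without CBPi_Treg 2 (0.315), after quantile normalization (0.054) or after cyclic loess (0.0947), and its direction turned without DMSO_Th0 1 (0.873).

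The remaining lists did not pass against Th0. The Treg signature (adjusted p = 0.72) had 4 rises, including IKZF4 at 1.32 (SE 0.13, adjusted p = 0.029 over all rows) and TNFRSF9 at 1.89 (SE 0.19, adjusted p = 0.029 over all rows), and 5 falls, including LAG3 at −1.01 (SE 0.13), adjusted over the list alone, with 3 falls without either DMSO_Treg array and 2 without DMSO_Th0 2. Costimulatory and inhibitory receptors (adjusted p = 0.584) had 3 rises and 8 falls, chemokine receptors and homing genes 2 rises and 6 falls, Th2 genes (adjusted p = 0.787) 2 rises and 2 falls, and NF-kappaB targets (adjusted p = 0.637) 5 rises and 4 falls, adjusted over the list alone. Receptor rises were 5 without CBPi_Treg 1, homing rises were 1 without any array but DMSO_Th0 2, and NF-kappaB rises were 3 without either DMSO_Treg array and 2 without DMSO_Th0 1. The TGF-beta and SMAD response (0.781), naive and quiescence genes (0.539), heat shock (0.236), acetyltransferases, deacetylases and bromodomain proteins (0.859), genes raised by BET bromodomain inhibitors (0.62), B cell markers (0.757), natural killer cell markers (0.066), CD4 T cell markers (0.787), red cell and platelet markers (0.37) and housekeeping genes (0.518) had these adjusted p-values by camera. Chemokine receptors and homing genes (adjusted p = 0.113) lay lower after median centring (0.0479), the filter on dim rows (0.0375) or without CBPi_Treg 1 (0.0375), and stood at adjusted p = 0.747 with an estimated correlation, all arrays as deposited. The monocyte and dendritic cell markers (adjusted p = 0.0651) lay lower after median centring (0.0489), the filter on dim rows (0.00535), or without CBPi_Treg 1 (0.0114) or DMSO_Th0 2 (0.00779), with ITGAX at −1.64 (SE 0.16, adjusted p = 0.029 over all rows). That list stood at adjusted p = 0.648 with an estimated correlation. MHC class II (adjusted p = 0.0518) lay higher after quantile normalization (0.0414), median centring (0.035) or cyclic loess (0.0419), without either DMSO_Treg array (0.0439) or without CBPi_Treg 1 (0.0267). It too stood at adjusted p = 0.648 with an estimated correlation.

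**Figure D3:**
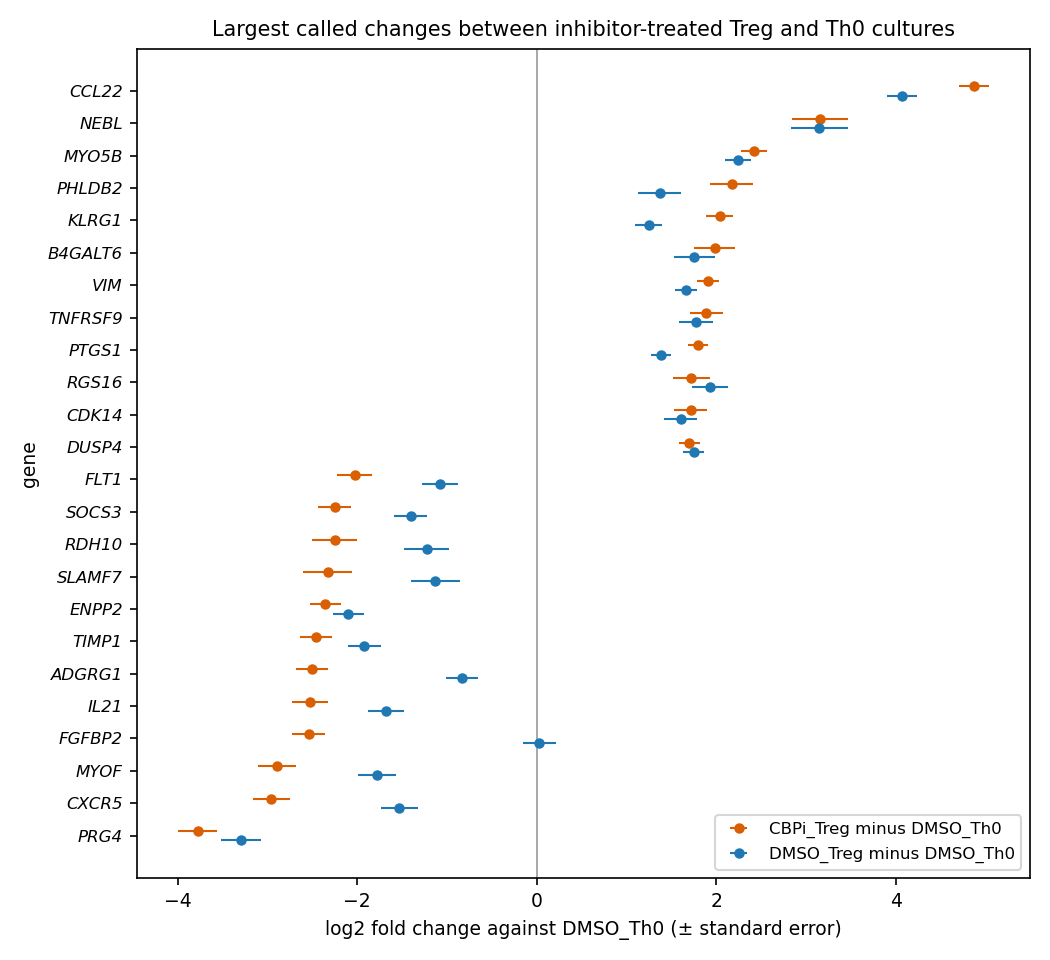
Log2 change from DMSO_Th0 (horizontal axis) of the 24 genes with the largest called changes in CBPi_Treg, with bars of 1 SE, in orange for CBPi_Treg and in blue for DMSO_Treg. CCL22 stood at 4.87 and 4.07 and PRG4 at −3.78 and −3.30, whereas FGFBP2 stood at −2.54 with the inhibitor and 0.03 without.

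Over all rows limma called 86 rows between CBPi_Treg and DMSO_Th0, 28 higher and 58 lower, and 68 of them named a single gene. Besides those above, the largest rises were those of NEBL, an actin-binding nebulin relative (3.16, SE 0.32), MYO5B (2.42, SE 0.15), B4GALT6, a lactosylceramide synthase (1.98, SE 0.23), and VIM (1.90, SE 0.12). PHLDB2 (2.17) was also called, but its 3 rows disagreed, at 0.31, 2.17 and −0.03. The largest falls besides CXCR5, FGFBP2 and IL21 were those of PRG4 (−3.78, SE 0.22), MYOF, a membrane-repair protein (−2.90, SE 0.21), ADGRG1 (−2.51, SE 0.18), TIMP1, a metalloproteinase inhibitor (−2.46, SE 0.18), ENPP2 (−2.36, SE 0.17) and SLAMF7, a lymphocyte activation receptor (−2.33, SE 0.27). There were 2359 rows at an unadjusted p under 0.05, and both arrays of one group lay above both of the other in 36.3% of rows against 33.3% by chance. The groups shared a single estimate of the spread. Their own spreads relative to it were 0.79 for DMSO_Treg, 1.05 for CBPi_Treg and 1.13 for DMSO_Th0. From the 4 compared arrays alone 2 rows were called and 1794 had an unadjusted p under 0.05. The 86 calls here and the 0 for the inhibitor therefore do not compare the sizes of these effects. The lower share of called rows was 67.4% as deposited and 57.1% of 205 rows after median centring. The count was 2 without either DMSO_Treg array, 1 without either CBPi_Treg array, 24 without DMSO_Th0 1 and 25 without DMSO_Th0 2. Of 575 list genes 102 fell and 21 rose, adjusted over the list alone, and 56 of the falls and 11 of the rises passed in a list with each array left out. Rises were 14 without CBPi_Treg 2 or DMSO_Th0 1. Camera called 13 of 31 lists lower and 1 higher, against 9 lists without CBPi_Treg 2 and 8 without DMSO_Th0 2, with 0 by an estimated correlation and 0 by fry (smallest adjusted p = 0.067).

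The last comparison asked how the inhibitor affected the genes that differed between Treg and Th0 cultures. Of the 12 rows called higher in Treg cultures, 6 were lower and 6 higher with the inhibitor, with a median change of −0.00. Of the 3 called lower, 2 were lower and 1 higher (median −0.26). CCL20 (−1.31, SE 0.16) and NRN1 (−1.06, SE 0.11) were among the former 6 and CCL22 (0.80, SE 0.17) and VIM (0.24, SE 0.12) among the latter, and 0 of the 15 rows were called for the inhibitor. PRG4 stood at −0.48 (SE 0.22) and ENPP2 at −0.26 (SE 0.17) with the inhibitor. Across all rows, which are not independent replicates, the inhibitor change and the Treg-to-Th0 change correlated at r = −0.26. Both changes contain the DMSO_Treg arrays with opposite sign, and unchanged simulated groups gave r = −0.50 with a pooled spread and r = −0.35 with each group's own spread. The covariance was −0.0183, against −0.0295 and −0.0184 in these simulations, which leaves differences of 0.0112 and 8.39e-05. With a different DMSO_Treg array in each comparison the correlation was −0.0344 and 0.0273 the other way round, and it ranged from −0.39 without DMSO_Treg 1 and −0.42 without DMSO_Treg 2 to −0.13 without CBPi_Treg 1. Of the 12 rows higher in DMSO_Treg than in Th0, 10 were also among the 28 higher in CBPi_Treg, against 0.0153 for independent lists, and all 3 lower rows were among the 58 lower, against 0.00791. These overlaps share the DMSO_Th0 arrays, which alone can make both comparisons move together, and no overlap of unchanged groups was simulated.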

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

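Cyclic loess and the setting without both CBPi_Treg 1 and DMSO_Th0 1 were chosen after the results had been seen, and the other settings before. The inhibitor comparison called 0 rows, against 1 after quantile normalization, 3 after median centring, 4 without dim rows, 17 with a single row per gene, 4 with array weights and 1 after cyclic loess. It called 0 under trend and robust settings, from the 4 compared arrays and without any array. Treg against Th0 called 15 rows, against 61 after quantile normalization, 64 after median centring, 62 without dim rows, 67 with a single row per gene, 51 after cyclic loess, 18 with array weights, 13 with trend and robust settings, 8 from the 4 compared arrays and 0 without both deviating arrays. Leaving out each array gave 0 to 8. CBPi_Treg against Th0 called 86 rows, against 258, 205, 191, 214 and 188 in the same order as the first 5, 31 with array weights, 84 with trend and robust settings, 2 from the 4 compared arrays and 0 without both deviating arrays. Leaving out each array gave 1 to 25. A 1.5-fold minimum changed none of the 3 counts.

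The correlation of the inhibitor change with the Treg-to-Th0 change (r = −0.26) was −0.0344 and 0.0273 with a different DMSO_Treg array in each comparison, which removes or reverses it. It ranged from −0.42 to −0.125 with an array left out, with an SD of 0.119.

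Camera called 20, 10 and 14 of 31 lists in the 3 comparisons as listed above. An estimated correlation left 0, 0 and 0 lists, in a test with little power on 3 residual degrees of freedom, and fry 1, 0 and 0 for a common direction. The mixed test of fry, which takes changes in either direction, passed 18, 19 and 25. For CBPi_Treg against Th0 the number ranged from 8 to 15 with an array left out. Among lists that passed with all arrays, the only one whose camera direction turned in any setting was cell cycle in that comparison, at adjusted p = 0.0304 with all arrays and from 5.98e-05 to 0.873 (lower) with an array left out. The medians of several lists that did not pass changed sign under another scaling. No named gene called over all rows with all arrays changed its direction in any setting. This says nothing of the inhibitor comparison, where 0 rows were called. Among named genes not called over all rows, sign changes over all comparisons and settings numbered 55 with arrays left out and 14 otherwise.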

Other observations

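The tests of the cytotoxic genes were chosen after that result had been seen, the test by cyclic loess rests on a setting added after the data had been seen, and the other tests were set before they were run. With the inhibitor, falls outnumbered rises among rows with an unadjusted p under 0.05, at 74.9% (56.7% to 80.5% with an array left out). Scaling between arrays could give this, and predicts a share of at most 55% after quantile normalization, where 60.3% was found (56.4% to 61.9% with an array left out). A distortion that depends on brightness predicts the same after cyclic loess, where 63.0% was found (56.0% to 67.5%). Both shares lay above the margin of 60% that had been set beforehand for ruling these out. That margin held no condition on leaving out arrays, and both ranges reach across it. Scaling may therefore account for part of the imbalance, and these arrays do not decide between scaling and an effect of the inhibitor.

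Across all rows the inhibitor change and the Treg-to-Th0 change correlated at r = −0.26, against −0.50 and −0.35 in simulated unchanged groups that share the DMSO_Treg arrays. Real group differences widen the changes and so weaken r, which makes the covariance the closer comparison. It was −0.0183, against −0.0295 with a pooled spread and −0.0184 (SD 0.00105) with each group's own spread. No correlation beyond that of the shared arrays was therefore shown. These shared arrays may explain the correlation: of the 200 rows most above Th0, picked with a DMSO_Treg array and measured against the other, the median change relative to all rows was 0.0104 (0.0364 and −0.0157 for each way round). The 200 rows most below Th0 had a median of −0.110 (−0.0973 and −0.122), with 60.5% and 61.5% lower, against 47.5% and 50.5% of the rows most above. This is in line with a fall of genes that are higher in Th0 cultures. With a single row per gene, SPRY1 (−1.75), RASGRP4 (−1.44), FOXP3 (−1.36), CCL20 (−1.31), BEND5 (−1.11) and NRN1 (−1.06) were called lower with the inhibitor and higher in Treg than in Th0 cultures, but both calls contain the DMSO_Treg arrays with opposite sign and no such overlap was simulated, so it may be chance and decides nothing.

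Cytotoxic effector genes lay lower with the inhibitor by camera (median −0.41, adjusted p = 1.84e-05, and adjusted p = 0.271 with an estimated correlation), with 6 of 15 genes falling, 1 rising and 8 not passing, adjusted over the list alone. A smaller share of natural killer or CD8 T cells would lower their other markers too, to a median of −0.204 or less, and the 7 such markers above the brightness minimum had a median of −0.0882 with an interquartile range of 0.553. Among these markers NCR3 (−0.97) and IL18RAP (−1.17) were lower, and IL18RAP is also in the Th1 list. NCAM1 (0.10), NCR1 (−0.09), TYROBP (0.03), CD8A (−0.13) and ZNF683 (−0.02) lay above −0.204. The range holds both outcomes, so a change in cell composition may contribute and was not excluded, and no sort beyond naive T cells is described in the sources used here. Scaling predicts a median within 0.1 of 0 after quantile normalization, where it was −0.291. Ruling scaling out required a median under −0.2 with each array left out too, and the range then was −0.317 to −0.185, so scaling may contribute and stays open.

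CBPi_Treg 1 and DMSO_Th0 1 differed from their partners along the same component, which held 53.2% of the variation within groups, and within-group differences of these groups correlated at 0.282. Upper quartiles were 8.36 and 8.31 on these arrays and 8.48 to 8.58 on the others. In replicate 1 relative to 2 the median of cell cycle genes was −0.37 in Th0 and −0.09 in CBPi_Treg, and that of housekeeping genes −0.36 in CBPi_Treg and −0.26 in Th0. Batches are not given in the sources used here, so the origin of this difference stays open.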
